A study of Mus musculus with 5 samples.

How the data were processed

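Droplet-based single-cell RNA sequencing (10x Chromium) was measured in 5 libraries of mouse trachea cells. The deposited files hold whole-number UMI counts per gene and barcode, per the file headers and values. The features carry human and mouse prefixes of a combined reference, plus sequences for mCherry and EGFP. The submitters' processing notes name Cell Ranger, STARsolo and Seurat and the builds GRCm38 and GRCh38. Which tool made the matrix, how barcodes were called and which filters came first is not given in the sources used here. Groups and days were taken from the labels. The series' design text speaks of 2 recipients, 1 per day, so the donor-derived and endogenous libraries of a day come from the same recipient. The replicates therefore differ in time after transplantation too. The main test left this pairing out, and a fit with the recipient as a block was an alternative. Its p-values measure the spread of 2 libraries within each group, moderated by that of other genes. Replicates were compared before use and shared 0 and 1 barcodes, with 5.90% and 1.67% of genes of at least 50 CPM 2-fold apart in the donor-derived and the endogenous pair.

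Barcodes with more than 10% human-mapped UMIs were left out (192, all in the control library), then barcodes under 500 genes or over 20% mitochondrial UMIs (38) and doublets called by Scrublet (48, 0.73%), which left 6554 cells. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (seed 1) gave 24 clusters of all libraries together. Clusters were named "-like" from marker lists by mean standardised expression. A name needed at least 3 detected markers and at least 1 of them among the 10 leading genes, with no other class holding more. A cluster that failed stayed unnamed, and goblet cells were joined to secretory-like cells. The tuft-like clusters were divided again, after seeing the data, which set apart 1 ionocyte-like sub-cluster and 1 left unnamed for its ciliated genes. Cluster 3 scored highest for hillock markers but passed only as secretory-like. Epithelial cells are the epithelial classes and unnamed clusters with Epcam in at least 50% of cells. The steps ran in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

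Raw UMI counts were summed per library and class, for classes with at least 20 cells in each library. Donor-derived and endogenous sums were compared with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, robust quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05). The SE beside a log2 fold change is that change, without its sign, divided by the square root of the F statistic. It is an approximation from the test and can lie below the counting error of genes with few counts. The difference between classes was tested as a class-by-group interaction with the library as a fixed term. Gene lists with at least 3 tested genes were tested with camera in limma 3.58.1 (preset correlation 0.01), with an estimated correlation and fry as alternatives, and were adjusted within a class. CPM are TMM-scaled. The control is 1 library, so the comparisons with it have no test. They count genes at least 2-fold apart in both recipients at 50 CPM and 10 counts, and give each list's median log2 difference (2 CPM added, genes of at least 20 CPM on average) as a percentile of 10000 random lists drawn from 20 expression bins. Shares have exact Clopper-Pearson 95% intervals and control levels exact Poisson ones, both for counting error only. A count of 0 allows up to 3 counts, which folds against it take per library on the TMM scale. The RNA of secretory-like cells in another class was estimated, after seeing the data, as a gene's secretory-like CPM times the class's Scgb1a1 level relative to secretory-like cells, an upper estimate. For EGFP in whole libraries and for G2 and M transcripts, shares of cells were also taken after thinning each cell to 5000 UMIs. EGFP shares by cluster and mCherry shares were not thinned.

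Named genes are, per class and direction, the 8 (5 in ciliated-like cells) with the largest called change in both recipients at a mean of 20 CPM or more, up to 4 called members of each list, the 6 largest folds per direction against the control, and a fixed set of lineage, Y-linked and reporter genes. Gene models, mitochondrial and ribosomal protein genes were not named by size. This gave 121, 114 and 87 genes in basal-like, secretory-like and ciliated-like cells, of which 89, 90 and 50 were called. Coordinates are from the GENCODE annotation of GRCm38 in the reference, matched by identifier for 210 of 213 named and 12561 of 12578 tested genes. Groups, gene lists, markers, tests and most alternatives were fixed before the data were examined. Alternatives included DESeq2 1.42.0, no filter, other scaling, clustering and cell filters, equal depth or cell numbers, and leaving out each library.

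Replicate pairing was checked from the correlation of same-day deviations from the group means, which was 0.243, 0.117 and -0.038 in basal-like, secretory-like and ciliated-like cells; it rests on the shared recipient. On simulated counts with 100 genes changed per fold, the edgeR test recovered 61%, 60% and 56% of 2-fold and 100%, 100% and 99% of 4-fold changes in basal-like, secretory-like and ciliated-like cells. False calls were 8, 5 and 12 of 169, 165 and 167 calls, among 11435, 11074 and 10306 genes. For donor-derived cells against the control the size rule recovered 36%, 20% and 25% of 2-fold and 72%, 73% and 74% of 4-fold changes. False calls there were 17, 2 and 13 of 125, 95 and 112 calls, among 15237, 15441 and 15540 genes. The interaction of secretory-like and basal-like cells recovered 17% and 95%, with 8 false calls of 120, among 12709 genes. The simulation used a single dispersion for all genes and gave the control no difference of its own from the endogenous libraries. Its changed genes were drawn from those of at least 20 CPM in endogenous cells, so recovery below that level was not measured. Human-mapped barcodes, immune and stromal cells and classes under 20 cells in a library were in no gene test. Genes with near-identical copies, such as H2-Q6 and H2-Q7, are uncertain, since reads may be split between copies.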

Results

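Single-cell RNA sequencing was carried out on tracheas of 2 mice that had received embryonic stem cell-derived basal cells (iBCs) after injury with the detergent polidocanol, and on the trachea of 1 mouse without injury or transplantation. Recipient tracheas were taken 40 and 56 days after transplantation. From each recipient, live cells (Calcein Blue positive) were sorted by GFP into a GFP-positive library, here donor-derived, and a GFP-negative library, here endogenous (n = 2 libraries per group). The control library (n = 1) was sorted on Calcein Blue alone. All files held UMI counts per gene and barcode. The donor-derived libraries held 1702 and 1743 barcodes with 25569394 and 21383107 UMIs on day 40 and day 56, the endogenous libraries 1336 and 1243 barcodes with 17756037 and 17732266 UMIs, and the control library 808 barcodes with 16580940 UMIs. In the control, 192 barcodes were mostly human-mapped and were left out, which left 7493284 UMIs. After filtering, 1693, 1731, 1300, 1219 and 611 cells were kept, with medians of 12783, 9999, 11175, 11772 and 10414 UMIs per cell.

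EGFP transcripts were seen in 56.2% (exact 95% interval 53.8 to 58.6) and 46.2% (43.8 to 48.5) of donor-derived cells on day 40 and day 56. In the endogenous libraries EGFP was seen in 0 of 1300 cells on day 40 (up to 0.231% at 3 counts, exact upper limit 0.28%) and in 1 of 1219 cells on day 56. In the control it was seen in 0 of 611 cells (up to 0.491%, exact upper limit 0.60%). These limits are on cells with an EGFP UMI, not on cells that carry EGFP, many of which gave none in the donor-derived libraries. After thinning to 5000 UMIs per cell the donor-derived shares were 30.4% and 26.8%. Cells of the donor-derived libraries in clusters of which 90% or more of recipient cells were endogenous gave an EGFP UMI in 15 of 54 cells (27.8%) and in 3 of 15. In the clusters of which 90% or more were donor-derived the shares were 56.7% and 46.1%. The median depths were 17631 and 16282 UMIs in the former and 12579 and 9958 UMIs in the latter. mCherry transcripts were seen in 9.27% and 9.30% of donor-derived cells. The Y-linked genes Eif2s3y, Uty and Ddx3y were detected in the epithelial cells of all 5 libraries, with Eif2s3y at 53.2 and 49.8 CPM in donor-derived, 47.2 and 44.9 CPM in endogenous and 47.1 CPM in control cells. Xist stood at 0.271 to 0.918 CPM, and how strands were counted is not given in the sources used here, so it cannot be told apart from its antisense gene Tsix. Of the pluripotency genes, Pou5f1 gave 3 and 2 UMIs and Nanog 2 and 1 UMIs over all donor-derived epithelial cells. The endogenous cells gave 0 and 2 UMIs of Pou5f1 and the control cells 1, with 0 UMIs of Nanog in these 3 libraries. At 0.119 and 0.094 CPM the donor-derived level of Pou5f1 lay within that of the other libraries, 0 to 0.15 CPM.

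Basal-like cells made up a larger part of the donor-derived than of the endogenous epithelium in both recipients. They were 42.7% (exact 95% interval 40.3 to 45.1) and 63.6% (61.3 to 65.9) of donor-derived epithelial cells, 32.5% (29.7 to 35.4) and 29.1% (26.0 to 32.3) of endogenous ones, and 10.8% (8.48 to 13.6) in the control. Ciliated-like cells were 2.44% (1.76 to 3.29) and 6.76% (5.63 to 8.05) of donor-derived, 21.3% and 24.1% of endogenous and 25.3% of control epithelial cells. Secretory-like cells were 38.8% and 27.2% of donor-derived, 34.6% and 34.2% of endogenous and 60.4% of control epithelial cells, so that the donor-derived share lay above the endogenous one on day 40 and below it on day 56. With each library clustered on its own it lay above on both days, at 35.4% and 24.9% against 25.1% and 21.5%. Hillock-like cells, a squamous type marked by Krt13 and Krt6a, were 0.297% and 0.058% of donor-derived against 4.79% and 7.70% of endogenous epithelial cells. This difference was not kept under every clustering. At resolution 2.0 the shares were 6.66% and 0.983% against 5.13% and 5.64%, and with each library clustered on its own 5.23% and 11.6% against 4.66% and 12.5%. Tuft-like cells were 0.119% and 0.058% against 2.58% and 2.36% after sub-clusters of ionocyte-like and unnamed cells were set apart, and 0.238% and 0.116% against 3.13% and 2.73% without that step. An unnamed epithelial cluster led by Ccl9, Ccl20 and Spib held 217 of 1682 donor-derived epithelial cells on day 40 and 27 of 1730 on day 56. It held 9 of 1086 and 8 of 805 endogenous ones, so the excess lay mainly on day 40. Each endogenous library clustered on its own also gave an unnamed cluster, of 9 and 8 cells, with Ccl9 and Ccl20 among its leading genes. Immune cells were 0.65% and 0.06% of donor-derived, 16% and 32.2% of endogenous and 0.33% of control cells. The GFP gate separates the donor-derived and endogenous libraries and can set these shares, and the control was sorted without that gate. With 2 libraries against 2, no exact test of a share can reach 0.05, so the intervals cover counting error only.

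**Figure D1:**
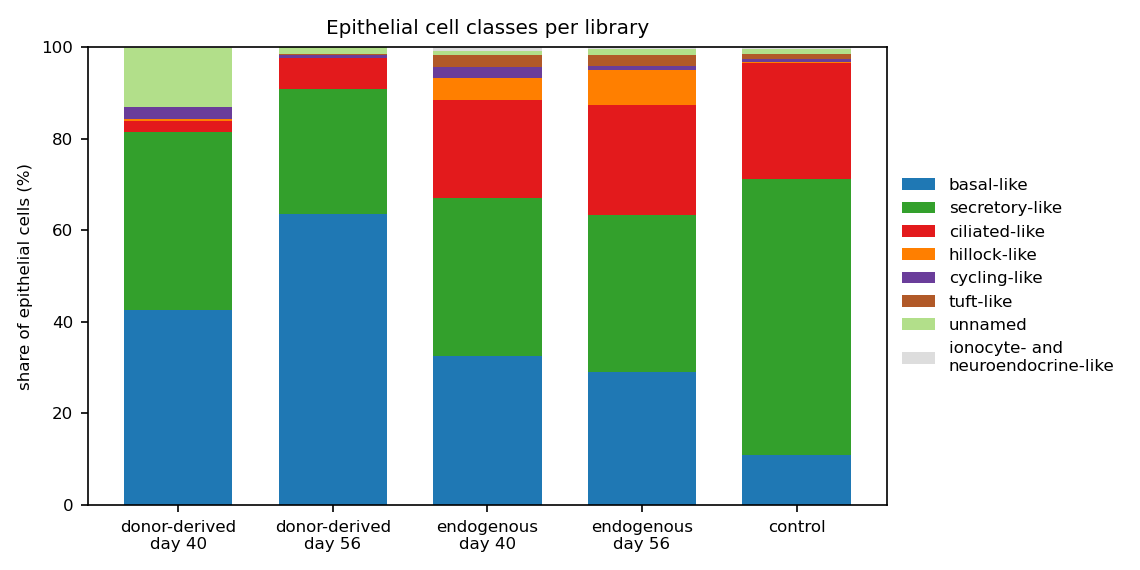
Share of each cell class among the epithelial cells of each library, in percent, as stacked bars without intervals. Basal-like shares were 42.7% and 63.6% in the donor-derived libraries and 32.5% and 29.1% in the endogenous ones, and ciliated-like shares were 2.44% and 6.76% against 21.3% and 24.1%.

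Donor-derived and endogenous basal-like cells were compared to find out how far cells grown from iBCs differ from the resident stem cells of the same trachea. Most donor-derived basal-like cells lay in clusters 0, 5, 7 and 13 and nearly all endogenous and control ones in cluster 2, so the groups were compared within the class but across clusters. Expression of the cell cycle inhibitor gene Cdkn2a (ENSMUSG00000044303, minus strand of chromosome 4, 89274471 to 89294653, GRCm38) was 121 and 103 CPM in the donor-derived libraries against 0 and 0.409 CPM in the endogenous ones and 0 in the control, a ratio of 660 with a counting interval of 118 to 26080 (edgeR adjusted p = 9.1e-05). The small heat shock protein gene Cryab (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636) was at 296 and 177 CPM against 0 and 1.23 CPM, a ratio of 456 (156 to 2212; adjusted p = 0.0045). Plet1 rose by 6.16 ± 0.31 (log2 fold change ± SE; adjusted p = 0.00013), from 0.856 and 2.45 CPM to 122 and 105 CPM. Calr3, which encodes a calreticulin, rose by 5.19 ± 0.25 (adjusted p = 0.00011). The DNA sensor gene Aim2 had no count in the endogenous cells and was at 50.8 and 43.9 CPM in the donor-derived ones, at least 45.5-fold higher as a ratio of the group means, with a floor of 3 counts per library. EGFP was at least 73.5-fold and mCherry at least 9.01-fold higher on the same floor.

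The genes with the largest falls in donor-derived basal-like cells included the sulfotransferase gene Sult1d1 (ENSMUSG00000029273, minus strand of chromosome 5, 87554645 to 87569027), with a log2 fold change of -6.49 ± 0.23 (adjusted p = 6.9e-05) and 19 and 12.9 CPM against 1437 and 1347 CPM. The imprinted kinase inhibitor gene Cdkn1c (ENSMUSG00000037664, minus strand of chromosome 7, 143458339 to 143461050) changed by -7.09 ± 0.28 (adjusted p = 6.9e-05), and the R-spondin receptor gene Lgr6 (ENSMUSG00000042793, minus strand of chromosome 1, 134983301 to 135105276) by -6.52 ± 0.34 (adjusted p = 0.00013). The glucuronosyltransferase gene Ugt2b34 fell from 113 and 101 CPM to 2.25 and 0.812 CPM, Vsnl1 from 69.0 and 60.1 CPM to 1.35 and 0.451 CPM, and Slc16a11 from 73.6 and 58.5 CPM to 1.01 and 0.180 CPM. Desmosomal Dsc3 fell from 24.0 and 25.4 CPM to 0.113 and 0.0902 CPM, a ratio of 245 (66.6 to 2040). Ly6k fell from 194 and 263 CPM to 4.51 and 0.541 CPM (adjusted p = 0.031, and 0.068 with the recipient as a block; 0.18 without the day 40 and 0.20 without the day 56 endogenous library; 0.056 at clustering resolution 0.5). With the hillock-like cells joined to the class, an alternative chosen after seeing the data, its adjusted p was 0.053.

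Of 12 transcription factors of the airway 4 fell and 1 rose (5 and 2 with the recipient as a block; 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.275). Among these and the basal cell factors, the lineage factor gene Nkx2-1 (log2 fold change -0.84 ± 0.13, adjusted p = 0.0077), Sox2 (-1.15 ± 0.13, adjusted p = 0.0023) and the basal cell factor gene Trp63 (-1.11 ± 0.15, adjusted p = 0.0044) fell, and the endoderm factor gene Gata6 rose by 1.82 ± 0.24 (adjusted p = 0.0053). Nkx2-1 and Trp63 were not called without the day 40 endogenous library (adjusted p = 0.074 and 0.065) or the day 56 one (0.099 and 0.073). Among the basal markers used to name the class, Dapl1, Dlk2, Aqp3 and Trp63 fell, while Dapl1 was at 259 and 306 CPM against 663 and 679 CPM. Without the day 40 endogenous library Dlk2 had an adjusted p of 0.065 and Aqp3 of 0.069. Krt5 (-0.06 ± 0.17, adjusted p = 0.89) and Krt15 (-0.36 ± 0.25, adjusted p = 0.5, and 0.045 with the recipient as a block) were not called. Imprinted Igf2r fell from 51.3 and 56.0 CPM to 5.63 and 6.41 CPM, and imprinted Sgce was at 18.6 and 11.9 CPM against 0 and 0.409 CPM, a ratio of 88.6 (15.8 to 3510). Of 3 measured genes typical of gut and liver, Pdx1, a factor of pancreas and duodenum, was at least 5.57-fold higher, Afp was at 12.2 and 7.04 CPM against 0 and 0.818 CPM, a ratio of 27.7 (7.57 to 231), and Hnf4g was lower, at 0.113 and 0 CPM against 3.71 and 2.04 CPM with a ratio of 60.4 (9.53 to 2515). All 3 were called. Without the day 40 endogenous library Pdx1 had an adjusted p of 0.055 and Afp of 0.11.

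Genes of xenobiotic metabolism fell as a group in basal-like cells. Of 24 measured members 11 fell and 0 rose (17 fell with the recipient as a block; 15 called when adjusted over the list alone), among them Cyp2f2, from 5021 and 5418 CPM to 1729 and 2178 CPM (camera adjusted p = 4.9e-11, and adjusted p = 0.704 with an estimated correlation). Of 10 secretory markers 5 fell and 0 rose (7 adjusted over the list alone), such as Cldn10, from 25.4 and 30.7 CPM to 1.01 and 0.812 CPM (camera adjusted p = 8.9e-07, and adjusted p = 0.704 with an estimated correlation). An upper estimate of RNA from secretory-like cells, scaled by Scgb1a1, came to 0.309 and 0.181 CPM for Cldn10 and 22.5 and 13.4 CPM for Cyp2f2 in the endogenous basal-like cells. For Scgb3a1, another of the 5, it came to 48.7 and 67.4 CPM, against measured levels of 52.8 and 49.5 CPM (adjusted p = 0.015, and 0.19 without the day 40 endogenous library). Of 13 transcripts encoded by mitochondrial DNA 11 fell (12 adjusted over the list alone, camera adjusted p = 0.000937, and adjusted p = 0.877 with an estimated correlation). At clustering resolution 0.5 the edgeR adjusted p of mt-Atp8 and mt-Nd3 was 0.061 and 0.063. Over all kept cells the median mitochondrial share of UMIs was 3.41% and 4.06% in the donor-derived libraries. It was 5.39% and 4.85% in the endogenous libraries and 6.19% in the control. How far the list follows this share was not tested in any class. Of 7 genes of MHC class II 3 rose (7 adjusted over the list alone; camera adjusted p = 0.000598, and adjusted p = 0.877 with an estimated correlation), with H2-Eb1 at 1391 and 798 CPM against 311 and 350 CPM. Without the day 40 endogenous library the adjusted p of H2-Eb1, H2-Aa and H2-DMb1 was 0.21, 0.24 and 0.21, and without the day 56 one that of H2-Eb1 and H2-Aa was 0.16 and 0.12. At clustering resolution 0.5 the adjusted p of H2-Eb1, H2-Aa and H2-DMb1 was 0.060, 0.0995 and 0.054, and at resolution 2.0 that of H2-DMb1 was 0.062. Of 24 interferon-response genes 3 rose and 1 fell (11 and 1 with the recipient as a block; 4 adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.897 with an estimated correlation). Isg15 was among those that rose, at 126.5 and 87.9 CPM against 46.5 and 53.6 CPM (adjusted p = 0.21 and 0.11 without the day 40 and the day 56 endogenous library, and 0.055 at resolution 0.5). Joining the hillock-like cells to the class, an alternative chosen after seeing the data, gave 0.062 for Isg15, 0.064 for H2-Eb1, 0.0997 for H2-Aa and 0.066 for H2-DMb1.

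Of 14 TGF-beta and BMP genes 3 rose and 1 fell (7 and 1 with the recipient as a block; 9 adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.704 with an estimated correlation). Tgfb2 rose from 15.4 and 14.3 CPM to 74.3 and 63.7 CPM, and Id3 from 8.56 and 21.7 CPM to 74.4 and 103 CPM (adjusted p = 0.056 at clustering resolution 0.5). Of 10 p53 targets 2 rose and 1 fell (3 adjusted over the list alone; camera adjusted p = 0.0076, and adjusted p = 0.762 with an estimated correlation). Cdkn2a, a member that rose, acts upstream of p53 rather than as its target. Without it, an alternative chosen after seeing the data, 1 of 9 genes rose and 1 fell, and the list was not called (camera adjusted p = 0.4815). Cdkn1a, the other member that rose, had an adjusted p of 0.094 and 0.096 without the day 40 and the day 56 endogenous library, 0.939 at resolution 0.5 and 0.978 with the hillock-like cells joined. Of 10 basal markers 1 rose and 4 fell (5 adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.877 with an estimated correlation). In all, edgeR called 1226 of 11479 genes at an adjusted p under 0.05, 467 higher and 759 lower in donor-derived cells. Each had the same direction in both recipients, which a call from 2 against 2 libraries nearly requires. The excess of lower calls was not kept without a filter on low counts (1252 higher and 1217 lower). It was smaller with the recipient as a block (958 and 1051). With the recipient as a block 2009 genes were called, without a filter on low counts 2469, without the day 56 donor-derived library 1931, without the day 40 endogenous library 327 and without the day 56 endogenous library 435. The secretory transcript Scgb1a1 stood at 1182 and 6562 CPM in donor-derived and 692 and 521 CPM in endogenous basal-like cells (adjusted p = 0.28).

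**Figure D2:**
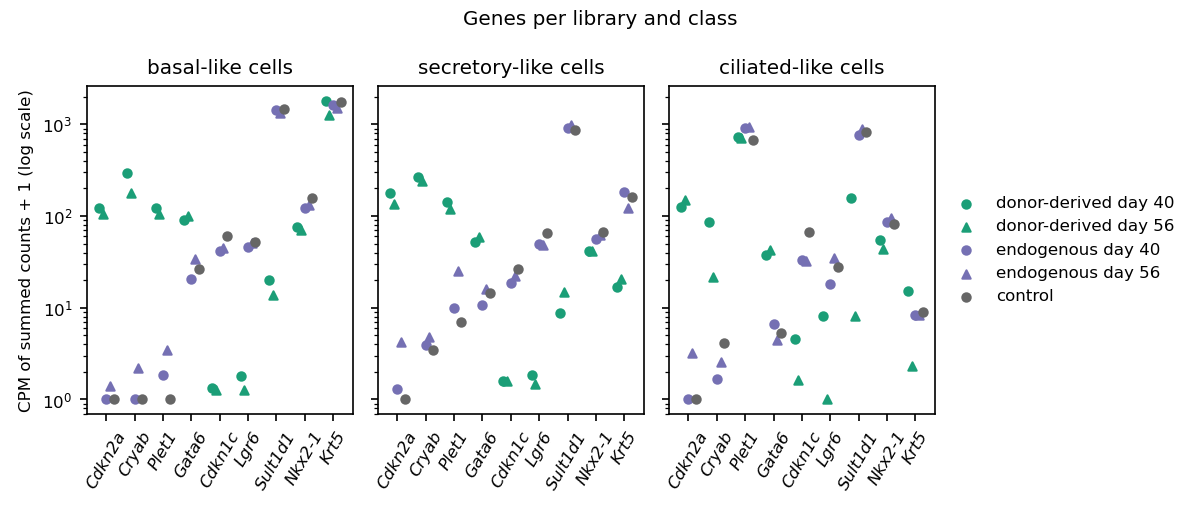
Summed expression (CPM plus 1, log axis) of 9 genes in basal-like, secretory-like and ciliated-like cells, 1 point per library, with circles for day 40 and the control and triangles for day 56. In basal-like cells Cdkn2a lies at 121 and 103 CPM in the donor-derived libraries and at 0 and 0.409 CPM in the endogenous ones, and Sult1d1 at 19 and 12.9 CPM against 1437 and 1347 CPM.

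Secretory-like cells, the club-cell type that releases Scgb1a1, were compared in the same way. Clusters 3 and 4 held most of the donor-derived cells and clusters 1 and 8 most of the endogenous and control cells. Cluster 3, which scored highest for hillock markers, held 488 of 653 donor-derived cells on day 40 and 84 of 470 on day 56. At clustering resolution 2.0 a hillock-like cluster of 129 cells had Areg and Upk3a, described below, among its leading genes. Cryab rose by 6.22 ± 0.19 (log2 fold change ± SE; edgeR adjusted p = 6.9e-06), from 2.88 and 3.78 CPM to 264 and 240 CPM. Clusterin, a secreted chaperone encoded by Clu (ENSMUSG00000022037, chromosome 14, 65968483 to 65981547), rose by 5.46 ± 0.28 (adjusted p = 3.5e-05), from 50.8 and 70.3 CPM to 2899 and 2532 CPM. The growth factor gene Areg rose by 5.65 ± 0.34 (adjusted p = 0.00029, and 0.204 at clustering resolution 2.0); the files name its identifier ENSMUSG00000029378 as Mcub, whereas the annotation gives it as Areg on chromosome 5, 91139599 to 91148432. Uroplakin gene Upk3a rose from 12.3 and 24.8 CPM to 463 and 925 CPM (adjusted p = 0.016; 0.11 and 0.12 without the day 40 and the day 56 donor-derived library, and 0.053 at resolution 2.0). Cdkn2a was at 178 and 135 CPM against 0.303 and 3.24 CPM (adjusted p = 0.026, and 0.22 with the recipient as a block; 0.23 and 0.19 without the day 40 and the day 56 donor-derived library, and 0.11 without a filter on low counts). EGFP was at least 124-fold higher as a ratio of the group means, with a floor of 3 counts per library.

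The secreted airway protein gene Bpifa1 (ENSMUSG00000027483, chromosome 2, 154142880 to 154149219) fell by 6.88 on the log2 scale (SE 0.58, adjusted p = 0.00043), from 41300 and 22040 CPM to 189.8 and 360.0 CPM, with 80570 CPM in the control (adjusted p = 0.069 without the day 40 donor-derived library). The antibacterial lectin gene Reg3g fell from 5104 and 4822 CPM to 138 and 102 CPM, trefoil factor gene Tff2 from 218 and 236 CPM to 1.08 and 2.65 CPM, and the fatty acid transporter gene Cd36 from 244 and 297 CPM to 3.33 and 4.33 CPM. With equal numbers of cells the adjusted p of Cd36 was 0.060 and that of Reg3g 0.081. With gate-typical cells, an alternative chosen after seeing the data that leaves out cells in clusters of the opposite gate, that of Reg3g was 0.26. Chad, a matrix protein gene, changed by -7.36 ± 0.21 (adjusted p = 6.9e-06), Lgr6 by -6.12 ± 0.25 (adjusted p = 1.8e-05) and Sult1d1 by -6.51 ± 0.33 (adjusted p = 6.7e-05). Cyp4a12b and Fmo6 also fell, to under 1 CPM from 81.2 and 70.9 CPM and from 80.4 and 54.5 CPM, but both have close relatives in the genome whose reads may be split between copies. Scgb1a1 itself was at 149900 and 269800 CPM in donor-derived and 218100 and 278600 CPM in endogenous cells (adjusted p = 0.81). Scgb3a2 was at 4869 and 15220 CPM against 34370 and 38120 CPM (adjusted p = 0.073, and 0.027 with the recipient as a block).

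Of 11 secretory markers 6 fell and 0 rose in donor-derived secretory-like cells (9 adjusted over the list alone; camera adjusted p = 1.5e-13, and adjusted p = 0.610 with an estimated correlation). Some of these markers were used to name the class. Of 25 xenobiotic-metabolism genes 10 fell and 1 rose (13 adjusted over the list alone; camera adjusted p = 1.2e-09, and adjusted p = 0.610 with an estimated correlation), among them Cyp2a5, from 4108 and 3295 CPM to 107.5 and 118 CPM. Of 22 mucosal defence genes 6 fell and 1 rose (11 and 1 with the recipient as a block; 12 adjusted over the list alone; camera adjusted p = 5.6e-08, and adjusted p = 0.610 with an estimated correlation). Mucin gene Muc5ac, the member that rose, was at 54.3 and 58.2 CPM against 32.1 and 19.4 CPM (adjusted p = 0.029; 0.075 and 0.063 without the day 40 and the day 56 donor-derived library, and 0.073 without the day 56 endogenous library; 0.0504 with thinned sums and 0.095 with equal numbers of cells). Of 9 basal markers 5 fell and 1 rose (7 adjusted over the list alone; camera adjusted p = 9.7e-06, and adjusted p = 0.610 with an estimated correlation), with Krt5 at 15.8 and 19.6 CPM against 184 and 120 CPM. Cluster 8, an endogenous and control cluster that held 0 and 1 donor-derived cells, carried Krt5. Without it, an alternative chosen after seeing the data, the log2 fold change of Krt5 went from -3.14 to 0.98, of Trp63 from -3.32 to 1.0 and of Dapl1 from -4.01 to 0.40, with adjusted p of 0.588, 0.276 and 0.546. Muc5ac was not called without it (0.56, adjusted p = 0.303).

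Of 6 ionocyte markers 3 fell and 1 rose in secretory-like cells (4 adjusted over the list alone; camera adjusted p = 0.00223, and adjusted p = 0.610 with an estimated correlation), with a median log2 difference of -0.04 on day 40 and -4.15 on day 56. The member that rose was the chloride channel gene Cftr, at 11.4 and 9.63 CPM against 1.97 and 1.62 CPM (adjusted p = 0.061 at clustering resolution 0.5), and among those that fell was the proton pump subunit gene Atp6v1c2, at 2.33 and 3.73 CPM against 68.0 and 76.8 CPM. Slc12a2, which encodes a sodium, potassium and chloride cotransporter, rose from 113 and 138 CPM to 395.5 and 342 CPM, and the sodium channel subunit gene Scnn1b fell from 15.3 and 28.4 CPM to 1.17 and 2.53 CPM. Of 9 Notch genes 4 fell and 0 rose (4 and 2 with the recipient as a block; 4 adjusted over the list alone; camera adjusted p = 0.0265, and adjusted p = 0.610 with an estimated correlation), with Hey1 at 0.750 and 0.241 CPM against 20.8 and 22.5 CPM. Of 8 Wnt genes 2 fell and 0 rose (2 and 1 with the recipient as a block; 3 adjusted over the list alone; camera adjusted p = 0.0307, 0.072 with the recipient as a block, and adjusted p = 0.610 with an estimated correlation), while the list's median was 0.06 and its mean -1.16. Of 13 transcripts encoded by mitochondrial DNA 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0103, and adjusted p = 0.929 with an estimated correlation).

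Of 25 interferon-response genes 2 rose and 0 fell in donor-derived secretory-like cells (3 and 1 with the recipient as a block; 1 adjusted over the list alone; camera adjusted p = 0.000159, and adjusted p = 0.929 with an estimated correlation). Of 14 class I genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.929 with an estimated correlation), such as B2m at 5038 and 2639 CPM against 1372 and 1664 CPM (adjusted p = 0.38 and 0.25 without the day 40 and the day 56 endogenous library, and 0.0513 at clustering resolution 2.0). Of 7 class II genes 0 were called (2 adjusted over the list alone; camera adjusted p = 0.0269, 0.0756 with the recipient as a block, and adjusted p = 0.929 with an estimated correlation), with Cd74 at 5119 and 2101 CPM against 819 and 1208 CPM. The median log2 differences of the 3 lists, interferon response, class I and class II, were larger on day 40 (1.82, 1.61 and 1.93) than on day 56 (0.51, 0.48 and 0.29). Of 12 airway transcription factors 3 rose and 3 fell (6 adjusted over the list alone), and the list was not called (median log2 fold change -0.13, mean 0.03, camera adjusted p = 0.553). Gata6 rose from 9.85 and 14.9 CPM to 51.1 and 58.8 CPM. Of 3 measured genes typical of gut and liver, Afp rose from 1.67 and 0.540 CPM to 16.2 and 17.0 CPM, and Pdx1 was at least 7.02-fold higher. Nkx2-1 fell by 0.55 on the log2 scale (adjusted p = 0.028; 0.13 and 0.23 without the day 40 and the day 56 endogenous library, and 0.14 in DESeq2). Altogether 1609 of 11255 genes were called, 712 higher and 897 lower, each in the same direction in both recipients, which such a call nearly requires. The excess of lower calls was small without a filter on low counts, at 1316 higher and 1345 lower. Without a filter on low counts 2661 genes were called, without the day 56 donor-derived library 2940, without the day 40 endogenous library 626 and without the day 56 endogenous library 761.

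Ciliated-like cells were few in the donor-derived libraries, 41 on day 40 and 117 on day 56, against 231 and 194 endogenous cells. Cluster 14 held 22 and 112 of the donor-derived cells and clusters 6 and 10 the endogenous and control ones, and 19 of the 41 donor-derived cells of day 40 lay in clusters 6 and 10. The interferon-induced chemokine gene Cxcl10 (ENSMUSG00000034855, minus strand of chromosome 5, 92346638 to 92348889) rose by 7.06 ± 0.30 (log2 fold change ± SE; edgeR adjusted p = 1.3e-05), from 0.672 and 0.951 CPM to 106 and 119 CPM. The forkhead factor gene Foxq1 (ENSMUSG00000038415, chromosome 13, 31556134 to 31560976) rose by 5.16 ± 0.23 (adjusted p = 1.3e-05), from 5.04 and 4.44 CPM to 149 and 181 CPM. Cdkn2a rose by 6.89 ± 0.53 (adjusted p = 0.0033), from 0 and 2.22 CPM to 125.5 and 148 CPM. Gata6 rose by 3.14 ± 0.31 (adjusted p = 0.002) and Wnt4 by 2.10 ± 0.17 (adjusted p = 0.00063). Afp had no count in endogenous cells and was at least 17.2-fold higher as a ratio of the group means, with a floor of 3 counts per library. Cdkn1c changed by -4.15 ± 0.48 (adjusted p = 0.0033). Scgb1a1 stood at 40.1% and 9.33% of its secretory-like level in donor-derived and at 11.2% and 12.9% in endogenous ciliated-like cells. The upper estimate of RNA from secretory-like cells, scaled by Scgb1a1, was in donor-derived cells 114 and 3.15 CPM for Cxcl10, 96.2 and 25.1 CPM for Foxq1, 71.4 and 12.6 CPM for Cdkn2a and 20.5 and 5.48 CPM for Gata6, against 36.4 and 42.0 CPM measured for Gata6. On day 40 the level of Cxcl10 was not above this estimate. Bpifb1 and Pon1 were called lower too, but in endogenous cells they stood at 119 and 106 CPM and at 41.6 and 61.8 CPM, near the estimates of 132 and 136 CPM and of 43.9 and 52.99 CPM. EGFP was at 28.2 and 105 CPM against 0 in both endogenous libraries (adjusted p = 0.24, and 2.0e-09 with the recipient as a block), at least 28.0-fold higher on day 40 and 110.0-fold on day 56 on the same floor.

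Interferon-response genes rose in donor-derived ciliated-like cells, 8 of 24 measured (19 adjusted over the list alone; camera adjusted p = 1.3e-21, and adjusted p = 0.395 with an estimated correlation), with Ifit3 at 226 and 199 CPM against 57.1 and 56.1 CPM. Of 7 class II genes 2 rose (4 with the recipient as a block; 7 adjusted over the list alone; camera adjusted p = 6.1e-08, and adjusted p = 0.665 with an estimated correlation). Of 14 class I genes 3 rose (9 adjusted over the list alone; camera adjusted p = 4.0e-05, and adjusted p = 0.703 with an estimated correlation). The median log2 differences of the 3 lists were 1.32, 2.54 and 1.37 on day 40 and 0.72, 0.95 and 0.35 on day 56. They were larger on day 40, when Scgb1a1 relative to secretory-like cells was also higher, as given above. Cd74 was at 5416 CPM in donor-derived ciliated-like and 5119 CPM in donor-derived secretory-like cells on day 40. RNA from secretory-like or basal-like cells was not set apart in these lists, so how far it adds to these rises is open. Tap1, which encodes a subunit of the transporter that supplies peptides for class I molecules, was at 195 and 125 CPM against 72.5 and 61.2 CPM. It was not called when either endogenous library was left out. Of 7 genes of the G2 and M phases 3 rose (7 adjusted over the list alone; camera adjusted p = 2.4e-10, and adjusted p = 0.395 with an estimated correlation), with Top2a at 21.1 and 18.7 CPM against 0.672 and 0.634 CPM. After thinning and without Hmgb2, an alternative chosen after seeing the data, at least 2 UMIs of the list were seen in 1 of 41 and 3 of 111 donor-derived and in 2 of 228 and 2 of 190 endogenous ciliated-like cells. Of 3 deuterosomal genes, which mark precursors that multiply their centrioles, 2 rose (2 adjusted over the list alone; camera adjusted p = 7.1e-08, and adjusted p = 0.395 with an estimated correlation). These were Ccno, from 4.03 and 4.12 CPM to 34.0 and 33.6 CPM, and Plk4, from 2.69 and 3.17 CPM to 24.6 and 22.6 CPM (adjusted p = 0.064 without the day 40 endogenous library). Of 5 cycling markers 2 rose (4 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.395 with an estimated correlation). The list of S phase genes, of which 8 were measured, was not called (median log2 fold change 0.23, camera adjusted p = 0.270).

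Of 22 genes of the motile cilium 1 fell (1 adjusted over the list alone; camera adjusted p = 0.0292, and adjusted p = 0.703 with an estimated correlation), with a median log2 difference of -0.61 on day 40 and -0.01 on day 56. This was Ccdc39, at 147 and 112 CPM against 273 and 304 CPM (adjusted p = 0.23 and 0.28 without the day 40 and the day 56 endogenous library). The ciliary master gene Foxj1 was at 459 and 554 CPM against 633 and 618 CPM (adjusted p = 0.49). Of 22 xenobiotic-metabolism genes 2 fell (4 with the recipient as a block; 5 adjusted over the list alone; camera adjusted p = 0.000359, and adjusted p = 0.703 with an estimated correlation). Of 11 secretory markers 1 fell (0 with the recipient as a block; 2 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.703 with an estimated correlation). Of 13 transcripts encoded by mitochondrial DNA 0 were called (4 adjusted over the list alone; camera adjusted p = 0.00425, and adjusted p = 0.703 with an estimated correlation). Of 14 immediate-early genes, which also respond to tissue dissociation, 1 rose (2 with the recipient as a block; 6 adjusted over the list alone; camera adjusted p = 7.8e-05, and adjusted p = 0.603 with an estimated correlation). Of 10 p53 targets 2 rose (2 adjusted over the list alone; camera adjusted p = 0.000605, and adjusted p = 0.644 with an estimated correlation). Without Cdkn2a 1 of 9 rose and the list was not called (camera adjusted p = 0.538). Of 8 NF-kappaB and cytokine genes 2 rose and 1 fell (3 adjusted over the list alone; camera adjusted p = 0.00863, and adjusted p = 0.703 with an estimated correlation). Of 8 TGF-beta and BMP genes 1 rose (2 with the recipient as a block; 1 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.703 with an estimated correlation). Of 20 mucosal defence genes 1 rose and 1 fell (4 adjusted over the list alone; camera adjusted p = 0.0203, and adjusted p = 0.806 with an estimated correlation). The median log2 difference of the mucosal defence genes was -0.08 on day 40 and -2.57 on day 56, and that of the secretory markers -0.58 and -2.76. Both lists hold genes of secretory-like cells. Relative to secretory-like cells, Scgb1a1 in donor-derived ciliated-like cells was higher on day 40 than on day 56, as given above. RNA from secretory-like cells was not set apart in these or any other list of this class. In total 405 of 10513 genes were called, 202 higher and 203 lower. Without the day 40 donor-derived library 2110 genes were called, without the day 56 one 1354, without the day 40 endogenous library 50 and without the day 56 one 80. With the sums thinned to the lowest library total 228 genes were called, with equal numbers of cells 244 and without a filter on low counts 791. With gate-typical cells, an alternative chosen after seeing the data, which leaves out the donor-derived cells in clusters 6 and 10, 1227 genes were called, 540 higher and 687 lower.

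Whether the donor-derived minus endogenous effect differed between classes was tested by the class-by-group interaction in edgeR over 12874 genes. It differed between secretory-like and basal-like cells for 207 genes, between ciliated-like and basal-like cells for 406 and between ciliated-like and secretory-like cells for 346. The Wnt inhibitor gene Sfrp1 rose in ciliated-like cells (log2 fold change 2.07) and fell in basal-like cells (-0.97), a difference of 2.97 (adjusted p = 5.6e-05). The p53 target Phlda3 rose in ciliated-like cells (1.0) and fell in secretory-like cells (-1.41), a difference of 2.32 (adjusted p = 0.0002, and 0.051 without the day 40 endogenous library). Without cluster 8 Phlda3 was called higher in donor-derived secretory-like cells (1.04, adjusted p = 0.0225), so that its opposite directions rest on that cluster being part of the class. Sfrp1 had an adjusted p of 0.072 in basal-like and 0.11 in ciliated-like cells without the day 40 endogenous library and of 0.092 in ciliated-like cells without the day 56 one. Phlda3 in ciliated-like cells (adjusted p = 0.049) had 0.63 and 0.38 without the day 40 and the day 56 endogenous library and 0.094 without the day 56 donor-derived library. With RLE size factors it had 0.0502, with doublets kept 0.084, with all barcodes 0.086, with thinned sums 0.13, with equal numbers of cells 0.34 and in DESeq2 0.50. For Cdkn2a the adjusted p of the 3 differences was 0.331, 0.425 and 0.76. Without the day 40 endogenous library 21, 39 and 23 genes differed, and without the day 56 one 25, 59 and 42. There were 523, 986 and 741 without the day 40 donor-derived library and 746, 910 and 989 without the day 56 one. Leaving out libraries was added here after seeing the data.

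Endogenous cells of the injured recipients were set against the trachea without injury to describe the recipient epithelium itself. The control is 1 library, so no test was made, and genes were counted that differed at least 2-fold from it in both recipients with at least 50 CPM and 10 counts. In basal-like cells 59 genes met this rule, 50 higher and 9 lower (39 and 18 with plain CPM; 116 genes without the day 40 library). In secretory-like cells 40 did, 39 higher and 1 lower (71 without the day 40 library), and in ciliated-like cells 49 did, 42 higher and 7 lower (76 without the day 40 library). Genes of antigen presentation led in every class. Cd74, the invariant chain of class II, was at 1213 and 1554 CPM in endogenous basal-like cells and at 1.5 CPM in the control (1 count, exact Poisson interval 0.038 to 8.36 CPM). H2-Aa had 0 control counts there and was at least 72.0-fold and 91.4-fold higher on a floor of 3 counts. H2-Q7 and H2-Q6, class I genes that are near-identical copies of each other and so uncertain as single genes, were at 645 and 729 CPM and at 145 and 162 CPM against 3.0 and 1.5 CPM. Lower in endogenous basal-like cells were Hells, at 13.4 and 8.59 CPM against 58.5 CPM (41.6 to 80.0), and Atad2 and Cdca7, which are expressed in dividing cells. Also lower were the ciliated marker gene Tppp3, at 38.8 and 44.2 CPM against 127.5 CPM, and Cldn3 and Igfbp5. The control sum of this class comes from 66 cells, and the Poisson intervals do not cover differences between cells. In ciliated-like cells Timp3 was at 32.2 and 33 CPM against 119 CPM, and the single lower gene in secretory-like cells was the potassium channel gene Kcnk2, at 48.5 and 51.3 CPM against 114 CPM.

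Donor-derived cells differed from the control in 341 genes in basal-like cells, 227 higher and 114 lower, in 312 in secretory-like cells, 205 higher and 107 lower (270 and 72 with plain CPM), and in 214 in ciliated-like cells, 119 higher and 95 lower. Without the day 56 library the counts were 525, 472 and 355, and without the day 40 library 350 in ciliated-like cells. Cd74 was at 4603 and 2681 CPM in donor-derived basal-like cells against 1.5 CPM in the control, and Iigp1, an interferon-induced GTPase gene, at 989 and 451.5 CPM against 0 counts (at least 220-fold and 100.3-fold). Krt14, a basal keratin gene, was at 3346 and 1768 CPM against 15 CPM (10 counts, 7.19 to 27.6 CPM). In secretory-like cells Ubd had 0 control counts and was at 898 and 160 CPM (at least 1334-fold and 238-fold). Lower than in the control were Bpifa1, at 190 and 360.0 CPM against 80570 CPM in secretory-like cells, and Apoe, at 1.58 and 1.93 CPM against 199 CPM. In ciliated-like cells Cd36 was at 12.9 and 0 CPM against 228 CPM. Both comparisons use the same control library, so genes found in both were not read as a shared effect.

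Over all 12 comparisons of a recipient library and class with the control, the median log2 difference was 6.30 to 9.13 for MHC class II genes, 2.37 to 4.25 for class I genes and 0.83 to 3.74 for interferon-response genes, each at percentile 100 of 10000 random lists matched on mean expression. The xenobiotic-metabolism genes had medians of -1.70 to -0.66 in donor-derived cells (percentile 0.00 in each) and of -0.42 to -0.19 in endogenous cells (0.00 to 2.89). Mucosal defence genes had medians of -1.44 and -1.04 in donor-derived basal-like and of -1.04 and -1.0 in donor-derived secretory-like cells (percentile 0.00 in each). In donor-derived ciliated-like cells the median was 0.35 on day 40 (99.84) and -2.01 on day 56 (0.00), and RNA from secretory-like cells was not set apart. In endogenous cells these medians were 0.90 and 0.66 in basal-like (100 in both), 0.10 and 0.75 in secretory-like (97.49 and 100) and 0.005 and 0.57 in ciliated-like cells (79.92 and 100). The endogenous libraries held 16% and 32.2% immune cells against 0.33% in the control.

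**Figure D3:**
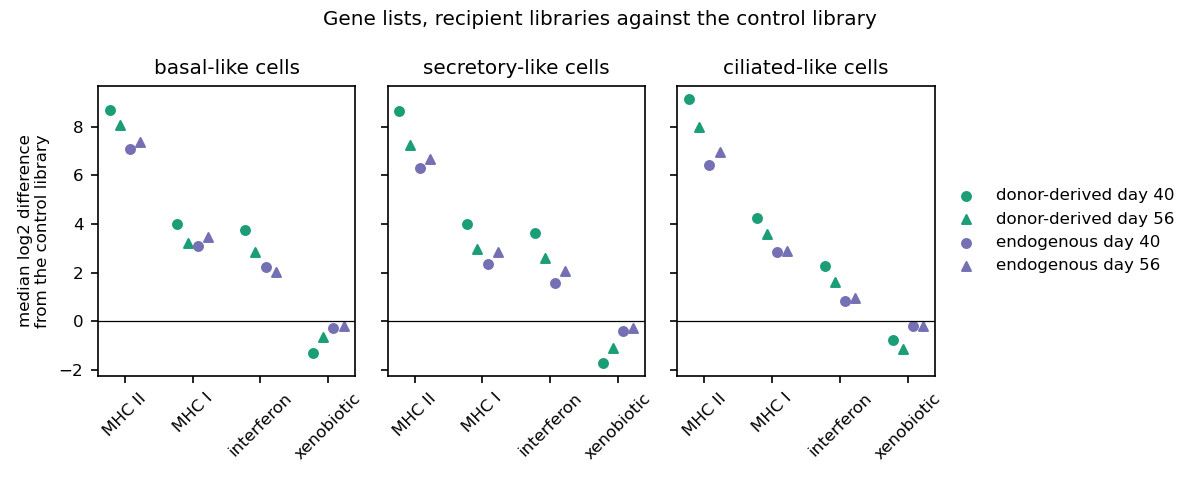
Median log2 difference from the control library of 4 gene lists, 1 point per recipient library and class, with circles for day 40 and triangles for day 56. The class II medians lie between 6.30 and 9.13 and those of xenobiotic metabolism between -1.70 and -0.19.

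Across genes, which are not independent replicates, the 2 donor-derived libraries had a Spearman correlation of 0.979 in basal-like cells and the 2 endogenous libraries of 0.978, against 0.911 to 0.928 between the groups. In secretory-like cells the pairs had 0.978 and 0.982, against 0.908 to 0.930 between the groups. In ciliated-like cells the endogenous pair had 0.983, and the donor-derived pair had 0.933, little above the 0.915 to 0.930 between the groups. Endogenous basal-like cells correlated with the control at 0.943 to 0.951 and donor-derived ones at 0.872 to 0.889. In secretory-like cells these values were 0.965 to 0.974 and 0.876 to 0.902, and in ciliated-like cells 0.962 to 0.967 and 0.901 to 0.903.

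A smaller share of donor-derived than of endogenous basal-like cells held G2 and M phase transcripts, and little of this difference was left without Hmgb2, a chromatin protein gene and the most abundant of the list. After thinning to 5000 UMIs, at least 2 UMIs of the list were seen in 13.8% (exact 95% interval 11.3 to 16.5) and 12.6% (10.7 to 14.8) of donor-derived, 24.6% (20.1 to 29.5) and 29.6% (23.7 to 35.9) of endogenous and 36.4% (24.9 to 49.1) of control basal-like cells. Without thinning the shares were 42.9% and 30.2%, 50.7% and 60.7%, and 54.5%. In ciliated-like cells the thinned shares were 7.32% and 14.4%, 8.77% and 11.6%, and 12.3%. Without Hmgb2, an alternative chosen after seeing the data, the thinned basal-like shares were 1.69% (0.875 to 2.93) and 1.04% (0.519 to 1.85) in donor-derived, 3.85% (2.06 to 6.49) and 0.435% (0.011 to 2.40) in endogenous and 1.52% in control cells. Hmgb2 was at 114 and 95.7 CPM against 180 and 207 CPM, with 189 CPM in the control (log2 fold change -0.93, edgeR adjusted p = 0.0093, and 0.070 and 0.10 without the day 40 and the day 56 endogenous library). It was the single member called among 8 measured genes of the list in basal-like cells (1 adjusted over the list alone). The list itself was not called (camera adjusted p = 0.990, and adjusted p = 0.996 with an estimated correlation), with a test direction down, a median log2 fold change of 0.09 and a mean of 0.06. Thinning left out 7, 41, 15, 4 and 0 basal-like cells of the donor-derived, endogenous and control libraries, and the clusters of dividing cells were not part of these shares. With those cells joined, an alternative chosen after seeing the data, the shares were 18.7% and 13.6% in donor-derived, 29.6% and 31.6% in endogenous and 40.0% in control cells. Without Hmgb2 these were 7.16% (5.43 to 9.24) and 2.15% (1.37 to 3.2), 10.2% (7.30 to 13.8) and 3.38% (1.47 to 6.54), and 7.14%, so that the donor-derived share lay below the endogenous one in both recipients, with overlapping intervals.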

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

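The tests of the antigen-presentation and Kdm5d patterns were chosen only after the results were seen, except the estimate of immune-cell RNA over all classes of the endogenous libraries, which was set before.

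The donor-derived minus endogenous effect differed between classes, by the interaction test, for 207 genes between secretory-like and basal-like, 406 between ciliated-like and basal-like and 346 between ciliated-like and secretory-like cells. Sfrp1 went opposite ways in ciliated-like and basal-like cells, with a log2 difference of 2.97. Phlda3 did so in ciliated-like and secretory-like cells, with 2.32 (1.93 without the day 40 endogenous library). For Phlda3 this rests on the Krt5-carrying cluster being part of the secretory-like class. Without that cluster its log2 fold change in secretory-like cells went from -1.41 to 1.04 (edgeR adjusted p = 0.0225), the same direction as in ciliated-like cells. The donor-derived minus endogenous share of secretory-like cells was 4.20 percentage points on day 40 and -6.99 on day 56, that of cycling-like cells 0.16 and -0.18, and the median log2 difference of the Wnt list in secretory-like cells 0.023 and -0.074. These 3 pairs of days differ in direction, and the difference was not tested. For the first of them this was not kept with each library clustered on its own, where the donor-derived share was higher on both days (35.4% against 25.1% and 24.9% against 21.5%). The cycling-like share on day 56 was also higher in the donor-derived library at resolution 0.5 (0.694% against 0.373%) and with all barcodes (0.746% against 0.486%). In the control library 53.894% of UMIs were human-mapped, all but a small part in 192 barcodes that were in no comparison. The labels give no source for them, and no explanation was tested.

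MHC class I and II genes lay above the control in every recipient library and class. In the donor-derived libraries, which held under 1% immune cells, the lowest median log2 difference was 2.96. This value cannot decide whether immune-cell RNA plays a part there. Control levels were low, such as 1.5 CPM for Cd74 in basal-like cells, so a small amount of such RNA can give a large difference. The share of immune-cell RNA was not estimated in the donor-derived libraries. In their epithelial cells outside the unnamed cluster, Ptprc, Tyrobp, Coro1a and Laptm5 stood at 0.10 to 0.62 CPM on day 40. On day 56 the range was 0.10 to 0.19 CPM. In endogenous macrophage-like and dendritic-like cells it was 575 to 2233 CPM. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 stood at 701 to 4603 CPM in donor-derived basal-like cells. These values argue against immune-cell RNA as the main source of these class II counts. In endogenous basal-like cells immune-cell RNA accounts for an estimated 1.49% or less of the Cd74, H2-Aa, H2-Ab1 or H2-Eb1 counts, with a highest upper 95% counting limit of 3.06%, whereas over all endogenous classes the estimate reaches 23.07%, which leaves a part open in ciliated-like cells and, on day 56, in secretory-like cells (9.89%, upper limit 12.9%). Scaling of the control does not account for it, since both lists lay at percentile 100 of matched random lists. Injury and transplantation remain open and untested, because there was 1 control library, which also differed in its gate.

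Kdm5d, a Y-linked gene, was lower in donor-derived basal-like (log2 fold change -4.60, edgeR adjusted p = 0.00832) and secretory-like cells (-3.26, adjusted p = 0.00138), and was not called in ciliated-like cells (-2.82, adjusted p = 0.13). Without the day 40 or the day 56 endogenous library the adjusted p in basal-like cells was 0.099 and 0.11. Loss of the Y chromosome is argued against by the other 3 Y-linked genes, whose lowest median over the classes was -0.315. A variant at the gene in the donor line, which a fall of -4.60 cannot show or exclude, stays open, since count tables hold no sequence.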

How the results depend on the processing

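Gate-typical cells, a class without its Krt5-carrying cluster 8, joined hillock-like cells, the G2 and M list without Hmgb2 or with cycling-like cells joined, tuft-like clusters without sub-clusters, the p53 list without Cdkn2a and the interaction without each library were chosen after seeing the data; for the changes below the cause was not tested unless given. Of 156 alternative values for the counts and shares 81 stayed within their limits, 72 moved and 3 reversed, and of 5394 for single genes and lists 4771 kept call and direction, 520 lost the call, 99 gained it and 4 reversed. Without a filter 2469, 2661 and 791 genes were called in basal-like, secretory-like and ciliated-like cells. With the recipient as a replicate block 2009 were called in basal-like cells, and the block changed no other class's count by over 1.5 times; where it moved the counts of a list in the report by more, or changed the call of a list or gene named there, its value is given beside it. The block called further lists, namely mucosal defence (adjusted p = 0.0217), Wnt (0.0377) and alveolar markers (0.0217) in basal-like, TGF-beta and BMP (0.0407), alveolar markers (0.00201) and squamous keratins (0.0338) in secretory-like, and squamous keratins (0.00215) and pluripotency genes (0.0255) in ciliated-like cells. Without it these had adjusted p of 0.163, 0.0541, 0.499, 0.0940, 0.166, 0.166, 0.0548 and 0.0516. Leaving out 1 library gave 327 to 1931, 626 to 2940 and 50 to 2110 genes, and 36 of 89, 42 of 90 and 14 of 50 named called genes were called in every such fit, in which the lone library is assumed to vary like the others. DESeq2 ended 6 of 89, 10 of 90 and 15 of 50 named calls and equal cell numbers 9 of 84, 9 of 89 and 11 of 40. Resolution 0.5 and joined hillock-like cells each ended 21 of 88 in basal-like cells, resolution 2.0 ended 9 of 89 and leaving out cluster 8 ended 8 of 88 in secretory-like cells and turned 4 more, of which 3 were no longer called, thinned sums ended 10 of 43 in ciliated-like cells, and each other alternative that left out no library ended at most 6. For the class differences the ranges were 21 to 746 (secretory-like and basal-like), 39 to 986 (ciliated-like and basal-like) and 23 to 989 (ciliated-like and secretory-like). In ciliated-like cells thinned sums gave 228, equal cell numbers 244 (both have fewer counts) and gate-typical cells 1227, which raises differences by construction. With an estimated correlation, and with fry, 0 lists were called in each class, against 8, 11 and 15. The secretory-like share difference of -1.40 points became 0.84 with doublets kept, 0.39 with all barcodes and 6.84 with each library clustered alone, and the ciliated-like one went from -18.08 to -16.95 at resolution 2.0. The hillock-like one of -6.07 became -1.56 at resolution 2.0, -11.23 with doublets kept and -0.20 with each library clustered alone, and the tuft-like one of -2.38 became -2.62, -2.98 and -2.97 at resolution 2.0, with doublets kept and with all barcodes, none of which used sub-clusters, and -2.76 without sub-clusters. Against the control, floors of 20 and 200 CPM and a 1.5-fold rule gave 157, 17 and 160 genes in endogenous basal-like, 75, 13 and 68 in secretory-like and 107, 18 and 126 in ciliated-like cells, and 731, 84 and 694, 610, 95 and 519, and 442, 63 and 432 in donor-derived cells. Leaving out 1 library gave 73 to 116, 42 to 71 and 60 to 76 endogenous and 400 to 525, 308 to 472 and 350 to 355 donor-derived genes. The G2 and M difference of -13.85 points was -5.95 at 3 UMIs -19.17 without thinning and -0.78 without Hmgb2, and with cycling-like cells joined and without Hmgb2 it was -2.14. The p53 list lost its call without Cdkn2a in basal-like and ciliated-like cells. In secretory-like cells without cluster 8, Phlda3 went to 1.041, Dapl1 to 0.403, Krt5 to 0.981 and Trp63 to 0.996. The day 40 donor-derived sum of ciliated-like cells rests on 41 cells, and how far this limits that class was not tested.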

Other observations

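The test of microfold genes was chosen only after the cluster's leading genes were seen, and the test of immune-cell RNA was set before its values were seen.

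The unnamed cluster, most of whose cells came from the day 40 donor-derived library, held transcripts of genes known from microfold cells. Those are epithelial cells that sample antigen over lymphoid tissue. The values below are of the cluster's donor-derived cells. On day 40 its 217 cells held Spib at 2138 CPM against 35.5 CPM in the other donor-derived epithelial cells, Gp2 at 331 against 20.5 CPM, Ccl9 at 4073 against 65.4 CPM, Ccl20 at 6981 against 298 CPM, Tnfaip2 at 1873 against 87.6 CPM and Sox8 at 243 against 6.94 CPM. On day 56 its 27 cells held Spib at 1791 against 3.37 CPM and Gp2 at 261 against 4.38 CPM. EGFP transcripts were seen in 54.4% and 59.3% of its cells, and on day 40 basal Krt5 stood at 61.1 CPM against 876.5 CPM, secretory Scgb1a1 at 26028 against 89494 CPM and ciliated Foxj1 at 3.93 against 22.8 CPM. The cells had medians of 17908 and 17149 UMIs against 12165 and 9965 in the other epithelial cells.

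A candidate explanation is a microfold-type gene program. Listed genes other than the cluster's leading ones had a median log2 difference of 1.77 (7 genes) and 2.53 (6 genes) on day 40 and day 56, and the lower of the percentiles among matched random lists was 99.97. Doublets with immune cells are argued against, since Ptprc, Tyrobp, Coro1a and Laptm5 had a median of 0.25% of their level in macrophage-like and dendritic-like cells. Coro1a, at 36.8 CPM on day 40, was 1 of these, and Aif1, which macrophages also express, was at 73.8 CPM against 696 CPM there. The cluster was found and tested in the same libraries, so this is a hypothesis.

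Further genes went opposite ways in a pair of classes, chosen here after their values were seen. Auts2 had a log2 fold change of 2.86 in ciliated-like and -1.32 in basal-like cells, a difference of 4.10 (edgeR adjusted p = 9.1e-06). Thbs1 had -2.0 in ciliated-like and 3.96 in secretory-like cells, a difference of -6.09 (adjusted p = 8.4e-06). Without single libraries the difference of Auts2 was 3.81 to 4.42, with adjusted p of up to 0.00896, and that of Thbs1 -6.31 to -5.78, with adjusted p of up to 0.00106.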
